A study of Mus musculus with 12 samples.

How the data were processed

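Polyadenylated RNA was sequenced from 12 mouse melanoma tumours, 3 from each of 4 passages (CBA, Balb/c-2, N2.1 and F0). Per the labels, the letters A to C name different tumours of a passage. The library names hold the flow cell: F0 A to C, N2.1 A to C and Balb/c-2 A (7 tumours) were on a first flow cell, and Balb/c-2 B and C and CBA A to C (5 tumours) on a second.

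The authors deposited 1 table of normalised signal, rounded to 3 decimals, for genes and for single copies of repeats in all 12 tumours. HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and the build mm10 are named in the submitters' processing notes. The role of each tool, the handling of reads that map to several places, the strand setting and the normalising tool are not given in the sources used here. The labels' protocols describe both directional and non-directional libraries without saying which was made, so reads of antisense or overlapping genes could not be told apart. Within each column, 100% of the deposited signal values were whole multiples of 1 step, within a tolerance of 0.1 reads. The deposited signal was therefore treated as read counts divided by 1 factor per library, between 0.8032 and 1.2097, and the reads were recovered by multiplication. Recovered depth ran from 34721735 to 59404254 reads per tumour. The table held 34436 genes and 662466 copies of transposable elements (TEs) in 1853 subfamilies, with none at 0 in every tumour, and no mitochondrial gene. Symbols and coordinates of 34364 gene IDs came from the GENCODE M21 annotation of the same build.

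Values are given as normalised read counts, with the SD over the 3 tumours of a group. Genes with a value of at least 10 in at least 3 tumours were tested (17491 genes), after adding a pseudocount of 1 and taking log2. limma 3.58.1 in R 4.3.3 was fitted with a mean per group over all 12 tumours (8 residual degrees of freedom), with a trended prior and robust moderation. Adjusted p values are two-sided and Benjamini-Hochberg corrected over all genes tested, called under 0.05. TE copies were summed to subfamilies, and the 1174 subfamilies that passed the same filter were tested in the same way as a family of their own. The 5 comparisons were N2.1, Balb/c-2 and CBA each against F0, Balb/c-2 against N2.1, and CBA against Balb/c-2.

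The tests, the comparisons, 28 gene lists and the rule for naming genes were set before the data were examined. The lists cover melanocyte differentiation, the dedifferentiated or invasive melanoma state, MHC class I and class II presentation, interferon response, nucleic acid sensing, T cells, NK and cytotoxic cells, B and plasma cells, macrophages and monocytes, neutrophils, dendritic cells, fibroblasts and collagen matrix, endothelium and pericytes, keratinocytes and epidermis, skeletal muscle, adipocytes, red blood cells, immune checkpoints and suppression, proliferation, hypoxia and glycolysis, oxidative phosphorylation, transposable element silencing, DNA demethylation and germline or cancer-testis genes, MAPK pathway output, p53 targets, sex-linked genes, and genes that differ between C57BL/6 and other strains. Each list was tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, corrected over the lists of a comparison. Named genes are the 6 largest rises and falls per comparison among called genes without overlap between tumours and with a mean of at least 100 in the higher group, leaving out predicted genes and pseudogenes by their symbols. Up to 3 members per called list were added, or the most abundant member where none was called, along with 11 genes named in every comparison. H2-K1, H2-D1, B2m, Cd274, Mitf, Sox10, Braf, Cdkn2a, Xist and Ddx3y are 10 of those 11. Some genes that the rule names are not reported here. For TE subfamilies the 4 largest rises and falls were named, along with 11 fixed subfamilies. Genes named outside this rule are marked as chosen after their values were seen.

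Shares of the signal in TE classes were compared with a two-sided permutation test over all 15400 partitions of the 12 tumours into 4 groups of 3, corrected over the classes. Between 2 groups of 3 the smallest exact permutation p is 0.1. A fold against a group with 0 reads is given as a lower bound against a floor of 3 reads over the group, and one against 1 to 3 reads with its exact 95% counting interval. Such intervals and floors cover counting error alone.

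The fits were tested on simulated counts for N2.1 against F0, drawn from the real means and library sizes with 200 of the 17491 genes changed. limma recovered 1% of the genes changed by a factor of 2 and 49% of those changed by a factor of 4, with 5 false calls among 55. edgeR 4.0.16 recovered 2% and 46%, with 2 false calls among 50. DESeq2 1.42.0 recovered 17% and 84%, with 45 false calls among 146. Among 1174 TE subfamilies limma recovered 12% and 65%. With the 38 interferon genes raised by a factor of 2, camera gave an adjusted p of 1.28e-23 (5.56e-05 with an estimated correlation) and called 0 of the other 27 lists. The simulated genes were drawn independently of each other. The 0 therefore says nothing of false list calls where the genes of a list vary together, as they can in real tumours.

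The alternatives tried were a pseudocount of 10, no low-value filter, a mean of at least 100, median-of-ratios scaling, quantile normalization, the flow cell as a covariate, the tumour letter as a block, array weights, a fit of the 6 tumours compared alone, edgeR and DESeq2 on the recovered reads, and leaving out each tumour in turn. After the data were seen, fits without F0 B, Balb/c-2 A and CBA B, with Balb/c-2 A alone for its group, of lists with the flow cell as a covariate, and with TE copies outside annotated genes were added. Balb/c-2 alone lies on both flow cells. With the flow cell as a covariate its changes against F0 and N2.1 are therefore those of Balb/c-2 A. Changes of CBA against Balb/c-2 are then those against Balb/c-2 B and C. The change of CBA against F0 adds the change of CBA against Balb/c-2 B and C to that of Balb/c-2 A against F0. No columns were left out. Repeats outside the TE classes (22499 copies) entered no comparison of the results.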

Results

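Polyadenylated RNA was sequenced from 12 tumours that descend from YUMM1.7, a mouse melanoma line of C57BL/6 origin with a Braf mutation and without functional Cdkn2a. Per the labels, cells of the line were placed in syngeneic mice to give the F0 tumours, and tumour cells were then passed on through further hosts. Tumours of 4 passages were sequenced, with 3 of each. The 3 tumours of a group belong to the same passage, so SDs, SEs and adjusted p values cover the spread between tumours of a passage. They do not cover the spread between repeated series of passages. CBA is the last of them in the order of the labels, after Balb/c-2, N2.1 and F0. The depth was 38140506, 46576846 and 45349749 reads in F0 A, B and C, and 51980170, 47667853 and 52355808 in N2.1 A, B and C. It was 53283840, 45062235 and 59404254 reads in Balb/c-2 A, B and C, and 49869848, 44974665 and 34721735 in CBA A, B and C. Values are normalised read counts, and 1 read corresponded to between 0.8266 and 1.2451 of them. Gene positions are on the build mm10.

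Tumours of a group did not resemble each other equally. The mean correlation with the other tumours of the group was between 0.904 and 0.924 in Balb/c-2 and between 0.942 and 0.973 in F0, N2.1 and CBA. Balb/c-2 A, B and C each correlated more highly with 1 tumour of another group (0.932, 0.945 and 0.937) than on average with their own. The main fit shares an estimate of spread between all groups, so SEs and adjusted p values of comparisons with Balb/c-2 can be too small. Genes with at least 1 read ranged from 19392 in CBA B to 26376 in Balb/c-2 A. On the first principal component, which held 24.6% of the variance, F0 B lay at 113 and the other F0 tumours at 40.3 and 27.4. Markers of B and plasma cells had a mean log2 level of 11.41 in Balb/c-2 A and between 3.16 and 6.70 in the other tumours. The Y-linked gene Ddx3y was at 272 in CBA B and between 1336 and 3907 in the other tumours.

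N2.1 was compared with F0 to ask what changed in the tumours over the passages from F0 to N2.1. Gbp4 and Cd274 rose, while Mcm6 fell. Gbp4, an interferon-induced GTPase (ENSMUSG00000079363, chromosome 5, 105115767 to 105139586), rose from 1838 ± 1375 in F0 to 40716 ± 4361 in N2.1 (SD, n = 3), a log2 change of 5.01 ± 0.77 (SE, adjusted p = 0.0041). Cd274, which encodes PD-L1 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), rose from 703 ± 502 to 11003 ± 1319, a log2 change of 4.36 ± 0.82 (adjusted p = 0.0095). The replication helicase gene Mcm6 (ENSMUSG00000026355, chromosome 1, 128331590 to 128359664) went from 8923 ± 1502 to 3856 ± 431, a log2 change of -1.20 ± 0.22 (adjusted p = 0.0085).

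Of 17491 genes tested, 1383 passed in N2.1 against F0, with 875 higher and 508 lower. The tumours of both groups did not overlap for 38.2% of the genes, where chance gives 10%. The count depended on single tumours: it was 815 without F0 A, 509 without F0 B, 894 without F0 C, 462 without N2.1 A, 874 without N2.1 B and 479 without N2.1 C. All 6 tumours were on the same flow cell. Quantile normalization moved the median log2 change of all genes from -0.015 to -0.115, and the share of calls that were higher from 63.3% to 51.1% (770 higher and 737 lower).

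Several genes that N2.1 expressed strongly had almost no reads in F0. Ifi202b, an interferon-inducible gene with close paralogs (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744), had 0 reads in F0 and 11739 in N2.1, at least 3715-fold higher. H2-Ea-ps, the class II gene that C57BL/6 mice do not express (ENSMUSG00000036322, chromosome 17, 34341959 to 34344645), had 1 read in F0 and 97652 in N2.1. Ifi44l had 2 reads in F0 and 3780 in N2.1, a ratio of 1794 (exact 95% counting interval 496 to 1.482e+04). Hormad1, a meiotic gene, had 1 read in F0 and 1523 in N2.1, a ratio of 1446 (interval 259 to 5.715e+04). Lcn2, which encodes lipocalin, rose from 74.2 ± 79.1 to 16993 ± 9733, and the mast cell tryptase gene Tpsab1 from 86.1 ± 109 to 17442 ± 3306, and Gbp2b had a log2 change of 8.53 ± 0.99. Lower in N2.1 were the cadherin gene Cdh26, from 545 ± 293 to 1.36 ± 2.35 (log2 change -8.18 ± 0.72, adjusted p = 1.25e-04), and Dlk1, from 524 ± 297 to 4.59 ± 3.98. Slitrk1 also fell, with a log2 change of -5.93 ± 0.85. Rxfp3 had 364 reads in F0 and 1 in N2.1, a ratio of 383 (interval 68.4 to 1.518e+04). How reads shared between paralogs were assigned is not known, so values of Gbp, H2 and Ifi202b genes carry that uncertainty. Bulk RNA does not separate host cells from tumour cells. For genes that C57BL/6 mice do not express, such as H2-Ea-ps, the strain of the host cannot be told apart from a change of the tumour cells. This holds for every comparison with F0.

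Among 38 interferon response genes 23 rose, 0 fell and 15 were not called, with 34 higher when adjusted over the list alone (camera adjusted p = 7.73e-21, adjusted p = 0.235 with an estimated correlation). The count was 14 without F0 B, 15 without F0 C, and 12, 14 and 13 without N2.1 A, B and C, and the median log2 change of the list, 1.97, was lowest without F0 B (1.345). Igtp rose by 4.38 ± 0.63 on the log2 scale (adjusted p = 0.0028) and Tgtp1 by 5.01 ± 0.80. Of 22 genes of MHC class I presentation 10 rose and 12 were not called, with 17 higher adjusted over the list alone (adjusted p = 3.69e-11, adjusted p = 0.235 with an estimated correlation). Tapbp rose from 16553 ± 6032 to 51976 ± 8242, Tapbpl from 1191 ± 388 to 4831 ± 305 and H2-T23 from 6970 ± 4411 to 44444 ± 12890. H2-K1 (64212 ± 46411 and 140024 ± 28527, adjusted p = 0.117) and H2-D1 (76692 ± 49405 and 191400 ± 39536, adjusted p = 0.0622) were not called. Of 13 genes of MHC class II presentation 2 rose and 11 were not called, with 7 adjusted over the list alone (adjusted p = 1.27e-05, adjusted p = 0.274 with an estimated correlation). Of 25 genes of immune checkpoints and suppression 11 rose, 1 fell and 13 were not called, with 16 higher and 3 lower adjusted over the list alone (adjusted p = 7.94e-06, adjusted p = 0.235 with an estimated correlation). Ido1 rose from 3.04 ± 2.90 to 229 ± 73.6, Lag3 from 254 ± 199 to 2020 ± 495 and Il10 from 19.8 ± 15.6 to 173 ± 40.4.

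Markers of several host cells were higher in N2.1 as lists. Of 16 genes of NK and cytotoxic cells 6 rose and 10 were not called, with 11 adjusted over the list alone (adjusted p = 3.01e-07, adjusted p = 0.274 with an estimated correlation), and Ifng rose from 47.6 ± 40.0 to 1112 ± 354. Of 22 T cell genes 2 rose and 20 were not called, with 10 adjusted over the list alone (adjusted p = 9.13e-07, adjusted p = 0.328 with an estimated correlation). Of 14 adipocyte genes 3 rose and 11 were not called, with 13 adjusted over the list alone (adjusted p = 1.87e-07, adjusted p = 0.244 with an estimated correlation), and Lpl rose from 461 ± 22.9 to 6421 ± 517. For 15 dendritic cell genes 4 rose, 11 were not called and 7 passed adjusted over the list alone (adjusted p = 7.09e-06, adjusted p = 0.235 with an estimated correlation), with Xcr1 at 51.9 ± 24.3 and 634 ± 365. For 12 neutrophil genes 4 rose, 8 were not called and 9 passed adjusted over the list alone (adjusted p = 8.64e-05, adjusted p = 0.235 with an estimated correlation), with Csf3r at 502 ± 88.5 and 2002 ± 137. For 23 macrophage and monocyte genes 3 rose, 20 were not called and 7 passed adjusted over the list alone (adjusted p = 0.0021, adjusted p = 0.274 with an estimated correlation). B and plasma cell genes (15, 2 rose, 13 not called, 2 adjusted over the list alone, adjusted p = 0.193), endothelium and pericytes (20, 0 called, adjusted p = 0.54), skeletal muscle (18, 0 called, adjusted p = 0.0767), red blood cells (6, 0 called, 1 lower adjusted over the list alone, adjusted p = 0.344) and keratinocytes (11, 2 rose, 1 fell, 8 not called, 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.065) were not called as lists. Without F0 B the median log2 changes of T cells (2.20 to 1.18), NK and cytotoxic cells (2.26 to 1.46) and neutrophils (3.04 to 1.996) were smaller, and so was that of MHC class II presentation (1.82 to 0.924). Of 25 fibroblast and collagen matrix genes 2 rose, 3 fell and 20 were not called, with 7 higher and 10 lower adjusted over the list alone (adjusted p = 0.344), and the median log2 change (-0.33) and the mean (0.07) differed in sign.

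Proliferation genes were lower in N2.1: of 30 genes 11 fell and 19 were not called, with 23 adjusted over the list alone (adjusted p = 4.36e-15, adjusted p = 0.235 with an estimated correlation). Of 21 p53 target genes 4 rose and 17 were not called, with 5 adjusted over the list alone (adjusted p = 0.0024, adjusted p = 0.235 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) rose from 4752 ± 2186 to 21037 ± 2874, and the death receptor gene Fas from 243 ± 118 to 1281 ± 633. Of 24 hypoxia and glycolysis genes 4 rose and 20 were not called, with 7 adjusted over the list alone (adjusted p = 1.27e-05, adjusted p = 0.2745 with an estimated correlation), and the median of 0.64 was 0.24 without F0 B. Of 20 genes of MAPK pathway output 3 rose and 17 were not called, with 7 adjusted over the list alone (adjusted p = 0.007, adjusted p = 0.3155 with an estimated correlation), and the median of 0.36 was 0.18 without N2.1 B. Of 16 nucleic acid sensing genes 2 rose and 14 were not called, with 2 adjusted over the list alone (adjusted p = 6.26e-04, adjusted p = 0.268 with an estimated correlation). Of 18 genes that differ between C57BL/6 and other strains 9 rose and 9 were not called, with 10 higher and 1 lower adjusted over the list alone (adjusted p = 9.13e-07, adjusted p = 0.235 with an estimated correlation). For oxidative phosphorylation, N2.1 against F0 gave a lower list of 28 genes with 0 called by limma (adjusted p = 0.0378, adjusted p = 0.701 with an estimated correlation), and its call ended without F0 A (0.0643), F0 C (0.171) or N2.1 B (0.397).

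Of 20 listed melanocyte genes, 7 were not tested: Tyrp1 was absent from the deposited table, and 6, with Tyr, Dct and Mlana among them, did not reach the low-value filter. Of 13 tested, 0 were called by limma over all genes and 4 were higher adjusted over the list alone (adjusted p = 0.0092, adjusted p = 0.235 with an estimated correlation). Mitf was at 340 ± 23.9 in F0 and 1001 ± 252 in N2.1 (adjusted p = 0.0555), and Sox10 at 1.97 ± 1.63 and 10.04 ± 5.003 (adjusted p = 0.388). Of 26 genes of the dedifferentiated or invasive state 1 rose, 2 fell and 23 were not called, with 7 higher and 3 lower adjusted over the list alone (adjusted p = 0.344). Of 29 genes of transposable element silencing 1 rose, 2 fell and 26 were not called, with 1 and 2 adjusted over the list alone (adjusted p = 0.129). Of 13 genes of DNA demethylation and the germline 1 rose, 1 fell and 11 were not called, with 1 and 2 adjusted over the list alone (adjusted p = 0.344), and the median (-0.03) and mean (0.01) differed in sign. Of 6 sex-linked genes 0 were called (adjusted p = 0.936), with a median of -0.39 and a mean of 0.37. Braf (adjusted p = 0.931) and Cdkn2a (0.663) were not called.

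**Figure D1:**
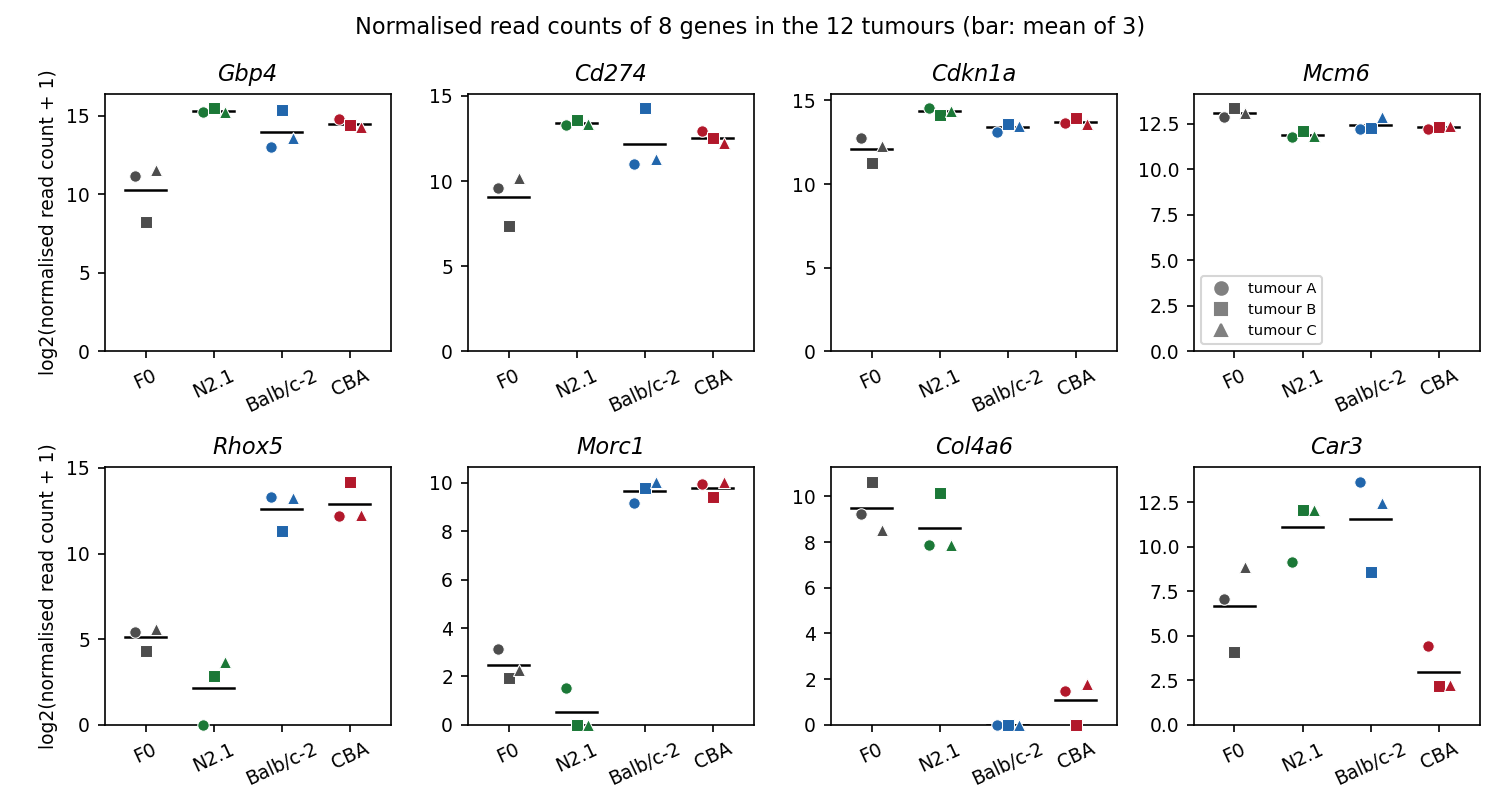
Normalised read counts of Gbp4, Cd274, Cdkn1a, Mcm6, Rhox5, Morc1, Col4a6 and Car3 on a log2 scale (a pseudocount of 1 added), with 1 marker per tumour (A circle, B square, C triangle) and a bar at the mean of 3 tumours. Gbp4 in N2.1 lies above every F0 tumour, and Rhox5 and Morc1 in Balb/c-2 and CBA lie above every F0 tumour.

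Balb/c-2 was compared with F0 to ask what changed by the passage named after a host of another strain. Rhox5, Magea3 and Morc1 rose, and Col4a6 and Loxl1 fell. Rhox5, a homeobox gene of the reproductive tract (ENSMUSG00000095180, chromosome X, 37804842 to 37808876), rose from 36.2 ± 15.0 to 7343 ± 4196 (SD, n = 3), a log2 change of 7.48 ± 0.91 (SE, adjusted p = 0.0012). Morc1, which takes part in TE silencing in male germ cells (ENSMUSG00000022652, chromosome 16, 48431237 to 48630900), rose from 4.83 ± 2.60 to 840 ± 244, a log2 change of 7.22 ± 0.51 (adjusted p = 2.58e-05). The collagen gene Col4a6 (ENSMUSG00000031273, chromosome X, 141165403 to 141474076) was at 858 ± 654 in F0 and had 0 reads in Balb/c-2, at least 1002-fold lower.

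In this comparison 614 genes passed, with 329 higher and 285 lower, and 21.3% of genes had no overlap between groups, where chance gives 10%. With quantile normalization the balance turned, with 327 higher and 406 lower. The count was 304 without F0 A and 227 without F0 B. Of the Balb/c-2 tumours only A was on the flow cell of F0, and with A alone for its group 383 genes passed (291 higher, 92 lower), of which 193 were shared. With the flow cell as a covariate, where the size of each change also comes from Balb/c-2 A, 261 genes passed. In that fit the calls of 16 of 31 named genes ended. Rhox5 (adjusted p = 0.0198), Morc1 (0.0025) and Col4a6 (0.0044) remained called.

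Magea3, whose family has many close copies, rose from 5.33 ± 3.94 to 341 ± 142 (log2 change 5.88 ± 0.74, adjusted p = 0.0014). Zfp985 had 2 reads in F0 and 797 in Balb/c-2, a ratio of 345 (interval 95.3 to 2856). Ifi202b was at least 2651-fold higher than in F0, and the ratio for Ifi44l was 1961 (interval 543 to 1.62e+04). Gbp2b rose from 48.1 ± 40.5 to 9369 ± 5171, Ido1 from 3.04 ± 2.90 to 202 ± 217 (log2 change from 5.46 ± 0.85 to 5.07 ± 1.26 and adjusted p = 0.0823 with the flow cell as a covariate) and Lpl from 461 ± 22.9 to 4298 ± 3002. Rasgrf1, a Ras exchange factor gene (ENSMUSG00000032356, chromosome 9, 89909908 to 90026977), went from 1429 ± 341 to 8.91 ± 2.16 (log2 change -7.17 ± 0.46, adjusted p = 1.14e-05), and the transcription factor gene Foxf2 from 286 ± 20.2 to 2.62 ± 2.28. Loxl1, a matrix crosslinking gene, went from 20417 ± 5834 to 6724 ± 1255 (log2 change -1.58 ± 0.24, adjusted p = 0.005, and -1.33 ± 0.34 with adjusted p = 0.0838 with the flow cell as a covariate). Cd274 was at 8178 ± 10193 and was not called (adjusted p = 0.0589).

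As lists, 17 of 28 passed. Of 38 interferon response genes 8 rose and 30 were not called, with 15 adjusted over the list alone (median 0.96, and 0.34 without F0 B, adjusted p = 1.38e-09, adjusted p = 0.365 with an estimated correlation). Lists of host cells were also higher, among them 5 lists of immune cells with 0 of their genes called by limma over all genes. Of 22 T cell genes 0 passed adjusted over the list alone (median 2.20, adjusted p = 1.83e-07, adjusted p = 0.365 with an estimated correlation), and of 16 genes of NK and cytotoxic cells 6 (median 1.65, adjusted p = 1.75e-05, and 0.365). Of 15 dendritic cell genes 7 did so (median 1.38, adjusted p = 2.46e-05, and 0.348) and of 12 neutrophil genes 5 (median 2.61, adjusted p = 5.09e-04, and 0.348). Of 15 B and plasma cell genes 0 did so (median 1.80, adjusted p = 0.0045, and 0.51), with a mean log2 level of 11.41 in Balb/c-2 A and of 5.51 and 3.84 in B and C. Without Balb/c-2 A that call ended (median -0.095, adjusted p = 0.973), and the median was 0.96 without F0 B, 3.02 without Balb/c-2 B and 3.15 without Balb/c-2 C. Without F0 B the medians of T cells and of NK and cytotoxic cells were 1.07 and 0.81, and that of T cells was 1.335 without Balb/c-2 A. Of 25 fibroblast and collagen matrix genes 8 fell, 1 rose and 16 were not called, with 12 lower and 3 higher adjusted over the list alone (median -0.91, and -0.48 without Balb/c-2 C, adjusted p = 0.0015, adjusted p = 0.348 with an estimated correlation). Of 14 adipocyte genes 3 rose and 11 were not called, with 8 adjusted over the list alone (adjusted p = 9.98e-08, adjusted p = 0.348 with an estimated correlation). Of 28 listed genes of DNA demethylation and the germline only 13 were tested. Of these 2 rose and 11 were not called, with 3 adjusted over the list alone (adjusted p = 0.0258, adjusted p = 0.311 with an estimated correlation), and without Balb/c-2 B the adjusted p was 0.127. The median of that list, 0.53, was 0.86 without F0 C, 0.96 without Balb/c-2 B and 0.85 without Balb/c-2 C. With the flow cell as a covariate 16 lists were called, 13 of them shared, and the calls of fibroblasts (adjusted p = 0.133), neutrophils (0.0916), p53 targets (0.202) and the germline list (0.125) ended. The interferon list stayed called (adjusted p = 2.56e-04, median 0.87) with 0 of its genes called by limma.

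CBA was compared with F0 to ask what the latest sequenced passage held relative to the first. Rhox5 and Slc2a1 rose, and Rgs5 and Tek fell, although these 4 calls ended with the flow cell as a covariate. Rhox5 was at 9463 ± 8110 and 36.2 ± 15.0 in F0 (SD, n = 3), a log2 change of 7.77 ± 0.91 (SE, adjusted p = 6.39e-04). The pericyte gene Rgs5 went from 1195 ± 557 to 298 ± 9.15 (log2 change -1.90 ± 0.30, adjusted p = 0.0038), and the angiopoietin receptor gene Tek from 119 ± 28.7 to 20.95 ± 9.632. Slc2a1, a glucose transporter gene, rose from 7515 ± 3068 to 28658 ± 2247 (log2 change 2.03 ± 0.39, adjusted p = 0.0119).

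In this comparison 882 genes passed, with 412 higher and 470 lower, and 29.5% had no overlap, where chance gives 10%. With quantile normalization 419 were higher and 414 lower. The count was 481 without F0 A, 483 without F0 B, 450 without CBA A and 512 without CBA C. CBA and F0 shared no flow cell, and with the flow cell as a covariate, which Balb/c-2 alone informs, 65 genes passed (39 higher, 26 lower, 50 of them shared). Of 33 named genes 10 stayed called in that fit, Morc1 (adjusted p = 0.0141) and Rasgrf1 (0.0037) among them, while Rhox5 (0.0588), Magea3 (0.0578), Rgs5 (0.303), Tek (0.305) and Slc2a1 (0.33) did not. The log2 change of Rgs5 went from -1.90 ± 0.30 to -1.46 ± 0.52, that of Tek from -2.53 ± 0.42 to -2.08 ± 0.75 and that of Slc2a1 from 2.03 ± 0.39 to 1.93 ± 0.74, so these calls ended largely with a larger error.

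Morc1 rose to 905 ± 195 (log2 change 7.35 ± 0.51, adjusted p = 1.65e-05) and Magea3 to 493 ± 311. Zfp985 had 1061 reads against 2 in F0, a ratio of 575 (interval 159 to 4755), and Ifi202b was at least 1674-fold higher. Igtp rose to 32254 ± 7548 (adjusted p = 0.0076), Irgm1 from 5025 ± 2735 to 26310 ± 3738 and Herc6 from 617 ± 323 to 3316 ± 317, but their calls ended with the flow cell as a covariate (adjusted p = 0.366, 0.37 and 0.409). The log2 changes went from 3.57 ± 0.63 to 2.82 ± 1.16 for Igtp, from 2.58 ± 0.42 to 1.77 ± 0.74 for Irgm1 and from 2.61 ± 0.45 to 1.76 ± 0.79 for Herc6. Rasgrf1 went to 3.80 ± 2.24 (log2 change -8.33 ± 0.46, adjusted p = 2.57e-06), Fjx1 from 747 ± 74.4 to 2.26 ± 2.52, and Ppfia4 (ENSMUSG00000026458, chromosome 1, 134296783 to 134332928) from 646 ± 131 to 3.81 ± 4.46. Foxf2 had 0 reads in CBA, at least 261-fold lower. Zfp985 (adjusted p = 0.0206), Ifi202b (2.65e-05), Fjx1 (0.016), Ppfia4 (0.0483) and Foxf2 (0.017) remained called with that covariate. For Cd274, CBA against F0 gave 6135 ± 1511 and an adjusted p of 0.0319, a call that ended without F0 A, F0 B, CBA A, CBA B or CBA C, with log2 changes of 3.78, 2.66, 3.31, 3.52 and 3.66. It also ended with the flow cell as a covariate (log2 change from 3.496 ± 0.818 to 1.74 ± 1.42, adjusted p = 0.634).

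As lists, 13 of 28 passed. Of 38 interferon response genes 15 rose and 23 were not called, with 25 adjusted over the list alone (adjusted p = 7.59e-22, adjusted p = 0.246 with an estimated correlation). Of 24 hypoxia and glycolysis genes 4 rose and 20 were not called, with 10 adjusted over the list alone (adjusted p = 3.89e-10, adjusted p = 0.246 with an estimated correlation). Of 20 endothelium and pericyte genes 6 fell and 14 were not called, with 11 adjusted over the list alone (adjusted p = 1.73e-05, adjusted p = 0.246 with an estimated correlation). Of 18 skeletal muscle genes 0 were called by limma over all genes and 0 adjusted over the list alone, with a median of -3.35 (adjusted p = 2.41e-05, adjusted p = 0.525 with an estimated correlation). Of 25 fibroblast and collagen matrix genes 1 fell and 24 were not called, with 8 lower adjusted over the list alone and a median of -0.58, or -0.89 without CBA C (adjusted p = 0.0015, adjusted p = 0.333 with an estimated correlation). The median of the interferon list, 1.62, was 0.94 without F0 B. With the flow cell as a covariate 19 lists were called, 10 of them shared. Among the lists gained, B and plasma cells were higher (median from -1.11 to 6.34, camera adjusted p = 1.33e-13). So were T cells (0.585 to 3.12, 1.14e-08) and adipocytes (-0.69 to 2.82, 0.0054). Macrophages and monocytes (-0.34 to -0.55, 0.0106) and neutrophils (-0.51 to -1.46, 0.0439) were gained as lower. That fit adds the distance of Balb/c-2 A from Balb/c-2 B and C, and Balb/c-2 A stood apart in B and plasma cell genes. Interferon response (median 1.47, adjusted p = 4.91e-07), hypoxia and glycolysis (0.76, 3.64e-04), endothelium and pericytes (-0.73, 0.0439) and skeletal muscle (-2.70, 0.0216) stayed called with 0 of their genes called by limma. The calls of fibroblasts (-0.12, 0.681), p53 targets (-0.065, 0.681) and the germline list (-0.27, 0.165) ended. Of 15 B and plasma cell genes 1 rose and 14 were not called, with 2 adjusted over the list alone (adjusted p = 0.476), and the median (-1.11) and the mean (0.13) differed in sign.

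**Figure D2:**
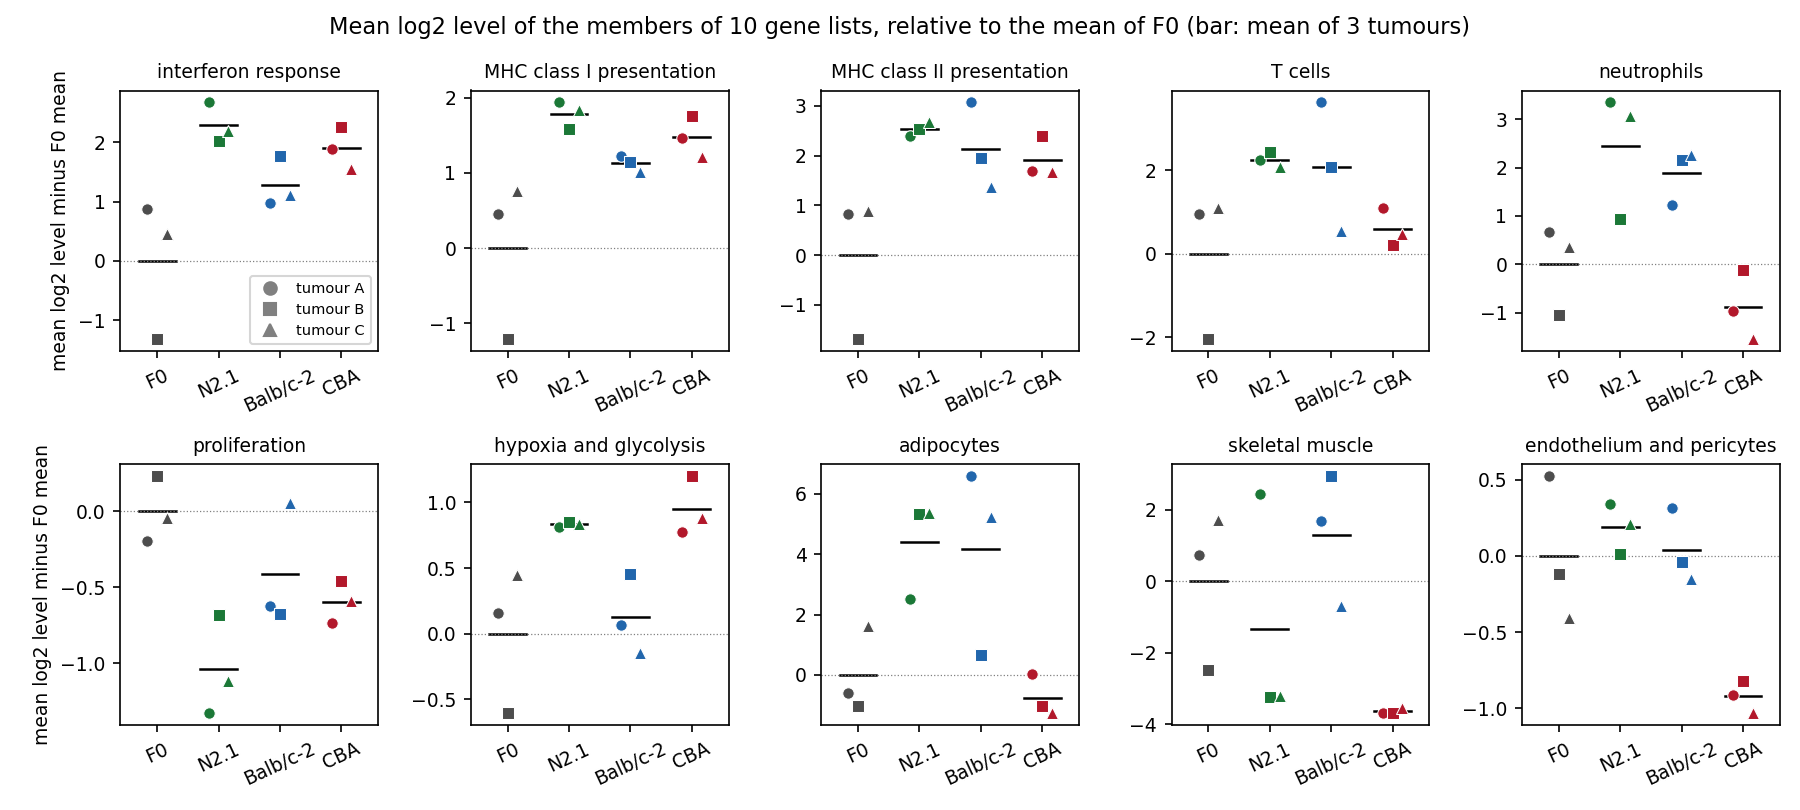
Mean log2 level of the members of 10 gene lists in each of the 12 tumours, as the difference from the F0 mean. Interferon response genes lie above the F0 mean in all 3 N2.1 tumours.

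Balb/c-2 was compared with N2.1 to ask what separated these passages. Rhox5 and Pet2 rose, and Rasgrf1, Col4a6 and Hormad1 fell. Rhox5 went from 5.95 ± 5.87 in N2.1 to 7343 ± 4196 in Balb/c-2 (SD, n = 3), a log2 change of 10.43 ± 0.91 (SE, adjusted p = 1.17e-04). Pet2, a testis gene of the X chromosome (ENSMUSG00000035395, chromosome X, 89403848 to 89409689), rose from 5.46 ± 4.83 to 3944 ± 785 (log2 change 9.80 ± 0.71, adjusted p = 3.41e-05). Rasgrf1 went from 4012 ± 1872 to 8.91 ± 2.16 (log2 change -8.59 ± 0.46, adjusted p = 6.26e-06).

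Here 406 genes passed, with 165 higher and 241 lower, and 20.1% had no overlap, where chance gives 10%. The count was 179 without N2.1 A, 179 without N2.1 B, 177 without N2.1 C, 1486 without Balb/c-2 B and 183 without Balb/c-2 C. With the flow cell as a covariate 117 genes passed, 89 of them shared, and with Balb/c-2 A alone, on the flow cell of N2.1, 299 passed. Magea8 and Ott had 0 reads in N2.1 and were at least 328-fold and 286-fold higher in Balb/c-2. Morc1 had 2 reads in N2.1 and 2878 in Balb/c-2, a ratio of 1313 (interval 363 to 1.085e+04). Hormad1 went from 480 ± 224 to 1.65 ± 2.86 (log2 change -7.94 ± 0.84, adjusted p = 3.83e-04) and Foxf2 from 243 ± 41.7 to 2.62 ± 2.28. Col4a6 was at least 588-fold lower. As lists, 12 of 28 passed. Of 13 genes of DNA demethylation and the germline 2 rose, 1 fell and 10 were not called, with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.0055, adjusted p = 0.325 with an estimated correlation). For DNA demethylation and germline or cancer-testis genes, Balb/c-2 against N2.1, the call ended without Balb/c-2 B (0.0609) or with the flow cell as a covariate (0.105), and the median of 1.12 was 0.74 without N2.1 B and 0.47 without Balb/c-2 C. Interferon response genes were lower (1 of 38 fell, 37 were not called, 2 lower adjusted over the list alone, adjusted p = 4.27e-07, adjusted p = 0.64 with an estimated correlation). Proliferation genes were higher as a list, with 0 of 30 called by limma over all genes and 0 adjusted over the list alone (adjusted p = 6.30e-08, adjusted p = 0.627 with an estimated correlation), and a median of 0.58 that was 0.93 without N2.1 B. With the flow cell as a covariate 13 lists were called, 9 of them shared, interferon response (5.47e-08) and proliferation (0.0094) among them.

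CBA was compared with Balb/c-2 to ask what separated the last sequenced passages. More genes fell than rose, Lpl, Ppfia4 and Fxyd6 among the former. The lipoprotein lipase gene Lpl (ENSMUSG00000015568, chromosome 8, 68880491 to 68907448) went from 4298 ± 3002 in Balb/c-2 to 316 ± 154 in CBA (SD, n = 3), a log2 change of -3.56 ± 0.50 (SE, adjusted p = 0.0089). Ppfia4 went from 528 ± 203 to 3.81 ± 4.46 (log2 change -7.26 ± 0.64, adjusted p = 7.38e-04). Fxyd6, a gene of an ion pump subunit (ENSMUSG00000066705, chromosome 9, 45370185 to 45396159), was at 125 ± 74.1 in Balb/c-2 and had 0 reads in CBA, at least 116-fold lower.

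Of the genes tested 182 passed, with 19 higher and 163 lower, and 12.7% had no overlap, where chance gives 10%. With quantile normalization 25 were higher and 100 lower. The count was 52 without Balb/c-2 A, which also leaves the second flow cell alone, 311 without Balb/c-2 B, 102 without CBA A and 57 without CBA C. With the flow cell as a covariate 63 genes passed, 51 of them shared. Of 18 named genes called, 13 lost their call in that fit, while Lpl, Ppfia4 and Fxyd6 were among the 5 that kept it. When each tumour was left out in turn, 15 of the 18 lost their call in at least 1 fit. For the matrix protease gene Mmp11, CBA against Balb/c-2 gave a rise from 724 ± 102 to 1887 ± 422 (log2 change 1.36 ± 0.23, adjusted p = 0.0169), a call that ended without Balb/c-2 A (0.0627), CBA A (0.0692) or CBA C (0.079), or with the flow cell as a covariate (0.061). Its log2 change stayed between 1.23 and 1.56 when 1 tumour was left out, and was 1.31 ± 0.25 with the covariate. With the covariate Balb/c-2 A no longer informs this comparison, so that fit gives the same log2 changes as the fit without Balb/c-2 A. As lists, 12 of 28 passed. Of 24 hypoxia and glycolysis genes 1 rose and 23 were not called, with 14 adjusted over the list alone (adjusted p = 1.41e-13, adjusted p = 0.228 with an estimated correlation). Of 14 adipocyte genes 2 fell and 12 were not called, with 11 adjusted over the list alone (adjusted p = 1.46e-12, adjusted p = 0.228 with an estimated correlation). Of 18 skeletal muscle genes 0 were called by limma over all genes and 18 were lower adjusted over the list alone (adjusted p = 7.87e-13, adjusted p = 0.326 with an estimated correlation). Of 20 endothelium and pericyte genes 2 fell and 18 were not called, with 10 adjusted over the list alone (adjusted p = 1.38e-07, adjusted p = 0.228 with an estimated correlation). Of 25 fibroblast and collagen matrix genes 1 fell (adjusted p = 0.421), and the median (0.27) and the mean (-0.19) differed in sign. With the flow cell as a covariate 9 lists were called, 8 of them shared, and those of hypoxia and glycolysis, adipocytes, skeletal muscle and endothelium and pericytes remained among them.

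Transposable elements were compared as subfamilies, 1174 of which were tested. In N2.1 against F0 27 were higher and 4 lower. IAP1-MM_I-int~IAP1-MM_LTR, of the IAP group of retroviral elements, rose from 131 ± 21.3 to 1155 ± 273 (SD, n = 3), a log2 change of 3.12 ± 0.43 (SE, adjusted p = 0.003), and 54.7% of its signal came from 1 copy outside annotated genes on chromosome X (86532957 to 86536227). MER58A fell by 1.21 (adjusted p = 0.0235), its most abundant copy lies in an exon of Postn, and outside genes its log2 change was 1.10. Of the 27 higher subfamilies 21 had their most abundant copy in a gene, 16 of these in an exon and 5 in a Gbp gene. The median share of that copy in the signal of its subfamily was 44.3% over the 27. Reads of a copy and of the gene around it cannot be separated here. The count was 13 without F0 A, 12 without F0 B, 20 without F0 C, 5 without N2.1 A and 17 without N2.1 C. The median over all subfamilies was 0.16, and -0.09 with quantile normalization.

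In Balb/c-2 against F0 26 subfamilies were higher and 3 lower, or 13 in all with quantile normalization, which moved the median over all subfamilies from 0.53 to -0.004. B2_Mm2, a short interspersed element, rose from 26822 ± 454 to 40261 ± 2143 (log2 change 0.59 ± 0.10, adjusted p = 0.0136, and 0.72 with adjusted p = 0.242 outside genes), and L1MdTf_I, a young L1 subfamily, from 257 ± 23.4 to 1046 ± 177 (2.01 ± 0.46, adjusted p = 0.0431). The count was 3 without F0 A, 7 without F0 B, 9 without F0 C, 11 without Balb/c-2 A and 269 without Balb/c-2 C. In CBA against F0 9 were higher and 1 lower (median over all subfamilies 0.22, and -0.06 with quantile normalization). All 9 had their most abundant copy in a gene. MTE2b, whose most abundant copy overlaps Gbp4, Gbp8 and Gbp9, was at 5180 ± 1127 in F0 and 21243 ± 3320 in CBA (log2 change 2.05 ± 0.23, adjusted p = 0.0011). Outside genes the log2 change of MTE2b was 0.40 ± 0.52 (adjusted p = 0.788), and 0 of the 8 higher subfamilies tested there were called by limma (106 of all subfamilies at an unadjusted p under 0.05). That count was 2 without F0 A, 4 without F0 B, 3 without CBA A and 1 without CBA B. With the flow cell as a covariate 191 subfamilies were called for Balb/c-2 against F0 (24 shared), 78 for CBA against F0 (5 shared) and 82 for Balb/c-2 against N2.1 (1 shared). Against N2.1, 1 subfamily was called in Balb/c-2, MMERVK10D3_I-int~MMERVK10D3_LTR (58.2 ± 7.86 and 325 ± 131, adjusted p = 0.0311). Without N2.1 A or N2.1 C limma called 0 (155 and 90 at an unadjusted p under 0.05), without N2.1 B 3, without Balb/c-2 A 3, without Balb/c-2 B 9 and without Balb/c-2 C 2, where edgeR called 2 and DESeq2 48 over all tumours. Against Balb/c-2, 2 subfamilies were called in CBA, among them RLTR6_Mm, which went from 3073 ± 540 to 935 ± 117 (log2 change -1.71 ± 0.27, adjusted p = 0.0295). The count was 1 without Balb/c-2 A, 1 without Balb/c-2 B and 0 by limma without Balb/c-2 C, CBA A, CBA B or CBA C (271, 73, 90 and 52 at an unadjusted p under 0.05), where edgeR called 0 and DESeq2 5 over all tumours.

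By class, the share of the signal differed between the 4 groups for SINEs and DNA transposons, but as shares of the TE signal alone neither passed (permutation adjusted p = 0.4697 and 0.0769), and a median over subfamilies ended the difference of DNA transposons (0.6597). SINEs held 2.04% ± 0.087 in F0, 2.13% ± 0.094 in N2.1, 2.55% ± 0.185 in Balb/c-2 and 2.29% ± 0.136 in CBA (SD, n = 3, permutation adjusted p = 0.0099). DNA transposons held 0.248% ± 0.005, 0.238% ± 0.007, 0.274% ± 0.014 and 0.279% ± 0.011 (permutation adjusted p = 0.0099). The share of all TEs was 3.99%, 4.45%, 5.24% and 4.54% (permutation adjusted p = 0.0553), that of LINEs gave a permutation adjusted p of 0.0722 and that of LTR elements 0.08. Without Balb/c-2 B the SINE value was 0.0518, and without Balb/c-2 C those of LINEs, LTR elements and all TEs were 0.0035, 3.90e-04 and 0.0031. The permutations leave out the flow cell, and F0 and N2.1 were wholly on the first and CBA wholly on the second. Balb/c-2 A, on the first, held 2.49% SINEs and 0.268% DNA transposons, above every F0 and N2.1 tumour (at most 2.23% and 0.254%), and Balb/c-2 B and C held 2.75% and 2.395% SINEs and 0.29% and 0.264% DNA transposons. F0 and N2.1 alone, on 1 flow cell, gave an exact permutation p of 0.4 for SINEs, 0.3 for DNA transposons and 0.1, the smallest possible, for LINEs, LTR elements and all TEs. LTR shares were between 1.19% and 1.252% in F0 and between 1.46% and 1.55% in N2.1.

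**Figure D3:**
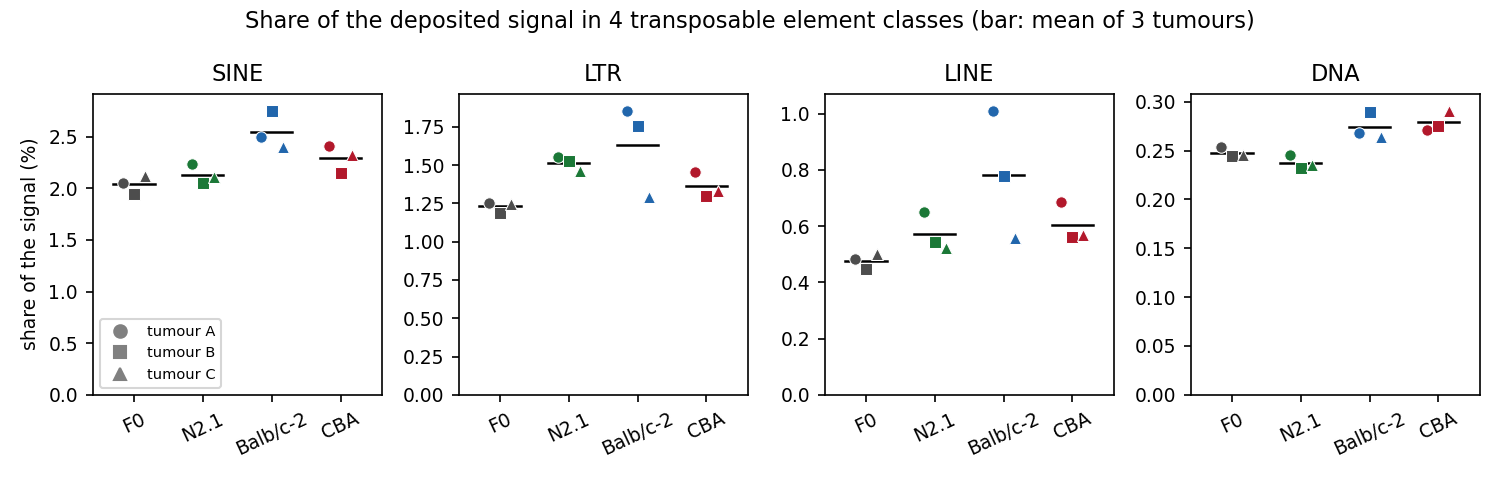
Share of the deposited signal, in percent, in SINE, LTR, LINE and DNA elements for each of the 12 tumours. SINE shares lie between 2.395% and 2.752% in Balb/c-2 and between 1.944% and 2.118% in F0.

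The 3 comparisons with F0 had calls in common. N2.1 and Balb/c-2 shared 302 genes changed in the same direction (205 higher, 97 lower) and 14 in opposite directions, where independent lists would share 16.5 higher and 8.28 lower. N2.1 and CBA shared 297 in the same direction and 30 in opposite ones, and Balb/c-2 and CBA 334 and 1. The F0 tumours were shared by these comparisons, so part of the overlap can come from them. Over all genes the log2 changes had correlations of 0.624, 0.424 and 0.611 in these 3 pairs, against 0.48, 0.443 and 0.469 on average in data simulated without a change between groups. In all 3 comparisons 105 genes were higher and 61 lower. Irf1 and Samhd1 were among the former and Wnt5a and Cd34 among the latter, chosen after their values were seen.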

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

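The tests of F0 B alone, of single immune cell types, of tumours of the same letter, of the flow cell, of Balb/c-2 A alone, of scaling as the whole cause of the TE rises and of TE copies outside annotated genes were chosen after the results they address or the data were seen.

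Repeats of the scRNA class lay outside the main measurement, and their share of the signal was above every F0 tumour in all 3 CBA tumours, at a ratio of 1.1 to F0 (0.0597% ± 0.0012 in CBA, 0.0544% ± 0.0025 in F0, SD, n = 3). This was 1 of 15 such tests of other repeat classes. The share also split by flow cell: it was 0.0591% and 0.0652% in Balb/c-2 B and C, which like CBA were on the second flow cell, and 0.0554% in Balb/c-2 A, and at most 0.0563% in F0 and N2.1, on the first. The flow cell and the passage cannot be told apart here.

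Interferon response genes were higher in N2.1 than in F0. Without F0 B, the F0 tumour with the lowest interferon level, the median log2 difference of the list was 68.1% of that with it, which argues against F0 B as the whole source. Quantile normalization moved the median log2 difference of the list from 1.97 (median SE 0.53) to 1.88, which argues against scaling between libraries as the whole source. Camera with a preset correlation kept the list called (adjusted p = 4.45e-21), but it compares the list with other genes, and with an estimated correlation the list was not called without that normalization either (adjusted p = 0.235). Immune cell markers were higher by 1.66 ± 0.65 (SE over 3 and 3 tumours) and the interferon list by 2.30 ± 0.70, and the difference of 0.64 ± 0.30 was 2.14 standard errors, past the bound of 2 set before that test. The bound was too lenient, because an SE over 3 and 3 tumours is itself uncertain and a mean over 6 cell types hides single types. T cell, NK and neutrophil markers rose on average by 2.26, 2.31 and 2.45, about as much as the interferon list. Macrophage and dendritic cell markers rose by 0.57 ± 0.14 and 1.59 ± 0.50 (SE). B cell markers differed by 1.17 ± 1.13, a change about as large as its error. If tumours of the same letter are set against each other, the interferon list rose by 0.56, 0.67 and 0.70 more than all immune markers. It rose by 0.51, -1.14 and 0.75 more than T cell markers, 0.06, -0.49 and 0.38 more than NK markers and -0.88, 1.38 and -0.95 more than neutrophil markers, without a common sign. More immune cells therefore cannot be told apart from a response of the tumour cells after passage, which bulk RNA leaves untested. Of 18 genes that differ between C57BL/6 and other strains 9 were also higher in N2.1. A difference in the strain of the host was not separated from either of these.

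27 TE subfamilies were higher in N2.1 than in F0. Summed over copies outside annotated genes, 40.7% of them (11 of 27) passed the test, and the median log2 difference went from 1.95 (median SE 0.31) to 1.29 (median SE 0.61). Reads of genes that overlap the copies are therefore a candidate source of part of these rises, although all 27 kept their sign outside genes. With quantile normalization all 27 kept their sign and their median log2 difference was 1.67 (median SE 0.31), 85.8% of that without it, while the median over all subfamilies moved from 0.16 to -0.09. This argues against scaling as the whole cause. Of the 27, 74.1% (20) passed, between the bounds of 50% and 75% set before that test, so a contribution of scaling to the other 7 cannot be told apart from a change of these subfamilies. The 11 fixed subfamilies were not called in N2.1 or CBA against F0. B2_Mm2 and L1MdTf_I alone of them were called in Balb/c-2 against F0. Release of TE silencing in the passaged tumours stays open.

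Rhox5 and Magea3, germline or cancer-testis genes, were called higher than in F0 in both Balb/c-2 and CBA. They were the only 2 such genes among 13 tested of the 28 listed. All 4 of these calls passed with quantile normalization, which argues against scaling. With the flow cell as a covariate, 2 of 2 calls passed for Balb/c-2, with log2 differences of 8.17 for Rhox5 and 6.52 for Magea3. Balb/c-2 A alone, on the flow cell of F0, gave the same differences. The size of the change in the covariate fit comes from that tumour, so these are not separate pieces of evidence. For CBA 0 of 2 calls passed: the log2 difference of Rhox5 went from 7.77 ± 0.91 to 8.80 ± 1.68 (limma adjusted p = 0.0588) and that of Magea3 from 6.16 ± 0.74 to 7.12 ± 1.35 (adjusted p = 0.0578), so the calls ended with the larger error. Relative to its error the smaller of these differences was that of Rhox5, at 5.23 standard errors above 0. Within Balb/c-2, Rhox5 was at 10017 in A on the first flow cell and at 2507 and 9505 in B and C on the second, and Magea3 at 505, 258 and 260. These values argue against the flow cell as the whole cause for CBA, although they rest on Balb/c-2 A as the 1 tumour of its group on the first flow cell. CBA and F0 shared no flow cell, so a contribution of the flow cell to the size of the CBA differences cannot be told apart from the passage. In N2.1 A, B and C Rhox5 was at 0, 6.11 and 11.74 and Magea3 at 0, 2.04 and 0, so no gain was seen by N2.1. A gain in the passages after N2.1 may account for both genes, which was not tested in repeated series of passages.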

How the results depend on the processing

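The fits without F0 B, Balb/c-2 A and CBA B, with Balb/c-2 A alone, of lists with the flow cell as a covariate, and with TE copies outside annotated genes were chosen after the data were seen. Counts are given in the order N2.1, Balb/c-2 and CBA against F0, Balb/c-2 against N2.1, and CBA against Balb/c-2, with limma on all tumours giving 1383, 614, 882, 406 and 182 genes and 31, 29, 10, 1 and 2 TE subfamilies. Unless a reason is named, the cause was not tested.

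A pseudocount of 10 kept all 10 counts within 1.5 times. Array weights gave 5977, 990, 7717, 649 and 767 genes, and 160, 75 and 219 TE subfamilies against F0 and 0 for CBA against Balb/c-2 (101 at an unadjusted p under 0.05). DESeq2 gave 2663, 1907, 1786, 1281 and 1035 genes and 64, 237, 63, 48 and 5 TE subfamilies. edgeR gave 100 genes for CBA against Balb/c-2, and 6, 2 and 0 TE subfamilies (100 at an unadjusted p under 0.05) in the last 3 comparisons. Fits of the 6 tumours compared, with fewer samples and the spread of those tumours alone, gave 2615 genes for N2.1 and 172 for Balb/c-2 against F0. They gave 138 genes for Balb/c-2 against N2.1 and 2 for CBA against Balb/c-2. TE subfamilies numbered 87, 6, 27, 0 and 0 (80 and 37 at an unadjusted p under 0.05 for the last pair). Fewer samples alone would not raise a count, as happened for N2.1. A mean of at least 100, with fewer genes tested, gave 552 genes for CBA against F0 and 72 against Balb/c-2, and 6 and 1 TE subfamilies in the last pair of comparisons. Without a filter 14 TE subfamilies were called for Balb/c-2 against F0. Quantile normalization gave 13, 3 and 5 TE subfamilies for Balb/c-2 against F0, Balb/c-2 against N2.1 and CBA against Balb/c-2, and median-of-ratios scaling 2 for Balb/c-2 against N2.1.

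With the flow cell as a covariate 261, 65, 117 and 63 genes and 191, 78, 82 and 1 TE subfamilies were called in the last 4 comparisons, and 18, 16, 19, 13 and 9 lists in all 5. With Balb/c-2 A alone, assumed to vary like the other groups, 383 genes were called against F0, and 293 and 149 TE subfamilies against F0 and N2.1. Without F0 B, Balb/c-2 A and CBA B 806, 336 and 505 genes were called against F0, 16, 3, 2, 4 and 1 TE subfamilies, and 11 lists for Balb/c-2 against F0. Copies outside annotated genes gave 15, 16, 0 (106 at an unadjusted p under 0.05) and 3 TE subfamilies in the first 4 comparisons.

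The tumour letters, which per the labels name different tumours, were not taken as pairs. Of 18 pairs with the same letter 7 had a correlation over 0.1, and their mean was -0.004 against 0.001 for other letters, but those of F0 with N2.1 had 0.203, 0.478 and 0.181. Of 12 tumours 5 correlated best with one of their own letter. With the letter as a block 28 calls of named genes ended, and 1 TE subfamily was called for CBA against Balb/c-2.

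Of the lists, 18, 17, 13, 12 and 12 were called. An estimated correlation gave 0, 0, 0, 0 and 0 (5, 3, 5, 1 and 4 at an unadjusted p under 0.05), and fry gave 5, 8, 1 and 0 in the last 4 comparisons (6 unadjusted in the last). Shares of the TE signal alone ended the differences of SINEs (permutation adjusted p = 0.4697) and DNA transposons (0.0769), and a median over subfamilies that of DNA transposons (0.6597). F0 and N2.1 alone gave an adjusted p of 0.4 for both, a design that cannot reach 0.05. Simulated data without a change gave a median overlap of 0, 0 and 0 for the 3 pairs of comparisons with F0, against 302, 297 and 334, but such data hold no true changes to share, so this says nothing of chance. The highest simulated overlaps were 770, 1515 and 0, with 1, 1 and 0 of 100 draws as large as in the data.

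Leaving out 1 tumour gave 462 to 894, 227 to 718, 450 to 661, 177 to 1486 and 52 to 311 genes. TE subfamilies ranged from 5 to 24, 3 to 269, 1 to 11, 0 to 9 and 0 to 1, and lists from 18 to 19, 15 to 18, 13 to 18, 9 to 17 and 9 to 16. Adjusted p of the shares ranged from 0.0035 to 0.1543 for LINEs, 0.0046 to 0.0518 for SINEs, 3.90e-04 to 0.1801 for LTR elements, 0.0031 to 0.0425 for DNA transposons, 0.1691 to 0.7453 for rolling-circle elements and 0.0031 to 0.1204 for all TEs. The direction of a list here is that given by camera, which compares the list with other genes, and can differ from the sign of its median. For p53 targets, CBA against F0, the median turned from 0.54 to -0.065 with the flow cell as a covariate, but the direction did not. Lists called in either fit changed direction in 13 cases. The first was hypoxia and glycolysis, Balb/c-2 against F0, without F0 B (adjusted p = 0.0295, with 0.7651 the highest when 1 tumour was left out). B and plasma cells, Balb/c-2 against F0, did so without Balb/c-2 A (0.9727, lowest 4.26e-06) and without the 3 tumours (0.3254). Next were adipocytes, Balb/c-2 against N2.1, without Balb/c-2 B (0.0494, highest 0.7391) and T cells, Balb/c-2 against N2.1, without Balb/c-2 C (0.0397, range 0.0332 to 0.9967). B and plasma cells, CBA against Balb/c-2, did so without Balb/c-2 A (0.8386, lowest 1.71e-05) and without the 3 tumours (0.7397). Then came oxidative phosphorylation, CBA against Balb/c-2, without Balb/c-2 B (0.002, highest 0.4886). With the flow cell as a covariate T cells, Balb/c-2 against N2.1 (2.78e-04), adipocytes, Balb/c-2 against N2.1 (0.0157) and B and plasma cells, CBA against Balb/c-2 (0.8448) did so. So did adipocytes, CBA against F0 (0.0054, other fits 0.321 to 0.8646) and transposable element silencing, CBA against F0 (0.0416, other fits 0.2955 to 0.9955). For CBA against Balb/c-2 the covariate gives the same log2 changes as leaving out Balb/c-2 A, so those cases of B and plasma cells are not separate. Single named genes kept their side of the threshold in 2211 cases, lost a call in 373 and gained one in 12. Of those called in either fit 0 changed sign, while uncalled ones such as Xist and Braf did in some fits. Single lists kept their side in 1537 cases, lost a call in 176 and gained one in 89.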

Other observations

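The values of this part were chosen after the data were seen. Xist, the RNA of the inactive X chromosome, was at 8911 in Balb/c-2 B, 1396 in F0 C and 1051 in CBA B, and at most 18.9 in the other 9 tumours. Skeletal muscle gene Acta1 ranged from 4.52 to 4024 within N2.1. The share of TE signal from copies in exons ranged from 58.0% in Balb/c-2 A to 77.7% in Balb/c-2 C.

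Each comparison of 3 tumours with 3 was set against the other splits of the same 6 tumours, and 10 splits are too few for a share under 0.05. For N2.1 against F0, 1 of 10 splits gave as many genes (1383, highest other 0), 1 as many TE subfamilies (31, highest other 0) and 6 as many lists (18, highest other 21), the real split included. For Balb/c-2 against F0 the numbers were 1 for genes (614, highest other 0), 1 for TE subfamilies (29, highest other 0) and 2 for lists (17, highest other 18). For CBA against F0 they were 1 (882, highest other 0), 1 (10, highest other 0) and 7 (13, highest other 17). For Balb/c-2 against N2.1 they were 1 (406, highest other 0), 1 (1, highest other 0) and 2 (12, highest other 16).

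For CBA against Balb/c-2 2 of 10 splits gave as many genes (182, highest other 3660), 2 as many TE subfamilies (2, highest other 55) and 2 as many lists (12, highest other 12). The split with 3660 genes set Balb/c-2 A, Balb/c-2 C and CBA B against the other 3 tumours, which points to a structure of the samples that crosses the groups and the flow cells. On the second principal component these 3 tumours lay at -46.5, -101.4 and -114.3 and the others at 28.1, -20.8 and -15.8. The mean log2 level of oxidative phosphorylation genes was 12.72, 13.09 and 13.03 in the first 3 and 11.62, 12.14 and 12.10 in the others.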
